A study of Mus musculus with 8 samples.

How the data were processed

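RNA sequencing libraries of C3H10T1/2 cells, an established multipotent mesenchymal cell line of mouse embryo origin, were compared after treatment with sphingosine 1-phosphate (S1P, a lipid that signals through G protein-coupled receptors) or vehicle. Per the labels, cells were kept without serum for 24 h and then treated for 24 h with 5 µM S1P or with the albumin vehicle. There were 4 vehicle libraries, numbered 1 to 4, and 4 S1P libraries, numbered 5 to 8. The labels do not state whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which can be technical.

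The deposited values are whole-number read counts per Ensembl gene for 18306 genes, with gene symbols and mm9 coordinates, and the authors deposited them without a normalisation factor. Per the submitters' processing notes, STAR 2.5.3a and the genome build mm9 were used. The tool that counted the reads and the annotation are not given in the sources used here. The deposited counts carry the word sense in their name, and the setting behind it is not explained there. The 8 columns of deposited counts summed to nearly equal totals, from 13750303 to 13761544, a spread of 0.0817%. Low counts followed a smooth distribution (misfit of 0.715 to 1.25 per library), whereas 6 simulated downward rescalings with rounding gave an uneven one (misfit of 2.12 to 15.2). Upward rescaling was not simulated. The totals resemble those of libraries reduced at random to a common size, so the depth before that step is unknown and the totals are the depth used here. At these totals, 3 counts correspond to 0.213 to 0.223 CPM (counts scaled to the library total), the upper limit that a count of 0 allows, for counting error alone.

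Each column was matched to its sample by title. Genes with enough counts were kept with the filterByExpr function of edgeR 4.0.16 in R 4.3.3 (minimum count of 10), which left 11844 genes. Composition factors were set with the trimmed mean of M-values (TMM), and CPM values given in the text use these factors. S1P was tested against vehicle with edgeR's robust quasi-likelihood test over all 8 libraries, with treatment as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 fold change is S1P minus vehicle, and its standard error (SE) was taken from the quasi-likelihood F statistic. Gene lists were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 22 of 26 lists that had at least 5 tested members. Beside each list, the members past the threshold were counted over all genes and also adjusted over the list alone. The test, the gene lists and the rule for named genes were chosen before the data were examined. An exact two-sided permutation test of each list's mean log2 CPM between the groups was added after the list results had been seen, and with 4 libraries against 4 its p cannot fall below 0.029.

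By that rule, the text names the 12 genes with the largest increase and the 12 with the largest decrease among changed genes whose groups did not overlap and whose mean was at least 2 CPM. It also names up to 4 changed members of each list with the largest change, or the 2 members with the highest mean where fewer than 2 had changed, and a fixed set of S1P receptor, sphingosine kinase and lineage genes. Other list members named below were chosen after their values were seen, and this is marked beside them. The values of 1 gene that the rule takes are not reported here. Symbols are those of the deposited table. Of the 18306 identifiers, 17497 were found in a current name table, and 1786 of these have another symbol there. S1pr4, S1pr5 and Myod1 were not found under the symbols used, and neither were 53 members of the lists in all. Further members were found but did not pass the count filter, and the number tested is given beside each list. The spans of Tagln, Sned1, Prg4, Cfb, Filip1l, Kif20a, Ccna2, Cdc45, Fdps, Pltp, Sphk2, Runx2, Brca1, Fancd2, mt-Co1 and mt-Cytb overlap another tested gene. How reads in such overlaps were assigned is not given, so the values of these genes are uncertain to that extent.

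The fit was tested on simulated counts for 11877 genes drawn from the means and totals of these libraries, with 200 genes changed by known folds. In this simulated S1P against vehicle comparison, 10% of 1.5-fold changes were recovered, 50% of 2-fold changes, 96% of 4-fold changes and 98% of 8-fold changes. False calls made up 7.3% of its calls. A change smaller than 2-fold was therefore often below detection with 4 libraries per group.

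The settings also tried were other composition factors, no filter and a stricter filter on low counts (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom, 1 surrogate variable from sva 3.50.0, leaving out each library in turn, glmTreat of edgeR against a 1.5-fold change, and list tests with an estimated correlation or with fry. Per-gene offsets for GC content and transcript length, and a fit without vehicle replicate 4 and S1P replicate 5 together, were added after the data had been seen. GC content and length came from the longest transcript of each gene in GENCODE M21, available for 98.2% of tested genes. That annotation is of a later genome build than mm9, so no coordinate of it was used. A processed pseudogene and its parent gene were aligned with blastn 2.17.0. No library was left out of the main comparison, and no 2 libraries of a group were alike within sampling noise (chi-square of at least 9.84 per gene).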

Results

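C3H10T1/2 cells, which can take on bone, fat, cartilage or muscle properties in culture, were profiled by RNA sequencing after 24 h with 5 µM S1P or with vehicle, to ask which genes respond to this lipid. The comparison held 4 vehicle and 4 S1P libraries. Each library summed to 13750303 to 13761544 counts, and 14907 to 15384 genes had at least a single count in a library. Across genes, log2 CPM values correlated at 0.929 to 0.988 within the vehicle group, 0.973 to 0.991 within the S1P group and 0.923 to 0.975 between groups. The leading principal component held 41.2% of the variance and separated the groups, with scores of -50.5 to -13.5 for vehicle and 14.3 to 35.2 for S1P. The next component held 29.0% and set vehicle replicate 4 apart at -50.8, against 14.6 to 36.5 for the other vehicle libraries. Mitochondrially encoded genes took 2.5% of the counts in vehicle replicate 4 and 3.45% to 3.83% in the other 7 libraries. The deviation of vehicle replicate 4 from the other vehicle libraries followed GC content across genes (r = 0.75, where genes are not independent replicates).

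After S1P, 24 of 25 tested G2/M genes, 14 of 26 G1/S and replication genes and 14 of 23 cholesterol genes rose, and none of these lists was called with an estimated correlation. Single smooth muscle and matricellular genes, among them Tagln, Acta2 and Ctgf, rose with them. The acute-phase gene Saa3, the cytokine Csf3, the proteases Mmp9 and Mmp14 and the small proteoglycans Dcn and Lum fell. In all, 1007 of 11844 tested genes (8.5%) changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 663 of them higher and 344 lower, and 334 rose and 186 fell at least 2-fold. At an unadjusted p under 0.05 in the same test there were 2942 of the 11844 genes. List counts at that unadjusted level, given below, are to be read beside this share. In 985 of the changed genes the groups did not overlap. Over all tested genes this held for 19.1%, against 2.86% by chance. Leaving out a library moved a count by over 1.5 times in 4 cases, to 1133 higher and 723 lower without vehicle replicate 4, 333 and 101 without S1P replicate 6, 408 and 151 without S1P replicate 7, and 360 and 108 without S1P replicate 8, and without vehicle replicate 4 and S1P replicate 5 together there were 1178 and 934. Higher genes made up 65.8% of the calls here and 54.6% with DESeq2, which called 967 higher and 804 lower.

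**Figure D1:**
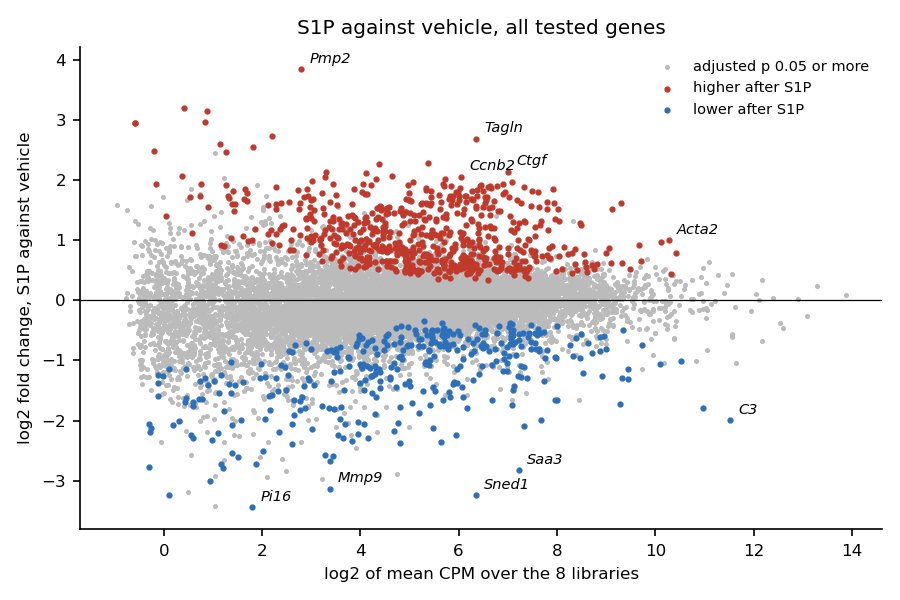
The log2 fold change of each of the 11844 tested genes (y axis, S1P against vehicle) is plotted against the log2 of its mean CPM over the 8 libraries (x axis), with the 663 higher genes in red, the 344 lower genes in blue and the rest in grey. Pmp2 at 3.84 and Pi16 at -3.44 lie near the upper and lower ends among the labelled genes.

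Among the largest increases by the naming rule, Pmp2, a fatty acid-binding protein of myelin (chromosome 3, 10179651 to 10184085 in mm9), rose 14.4-fold, from 0.892 ± 0.234 to 12.95 ± 5.44 CPM (SD, n = 4 per group; log2 fold change 3.84, SE 0.39, edgeR Benjamini-Hochberg adjusted p = 0.00247). Its neighbour Fabp5, another fatty acid-binding protein (chromosome 3, 10012348 to 10016807), rose 4.86-fold, from 14.1 ± 2.84 to 68.4 ± 26.8 CPM. Tagln, an actin-binding protein of smooth muscle (chromosome 9, 45737511 to 45744341), rose 6.44-fold, from 21.8 ± 7.09 to 141 ± 78.0 CPM (edgeR Benjamini-Hochberg adjusted p = 0.0039). The serpin Serpinb6b rose 6.67-fold, the adhesion molecule Mcam 5.87-fold, the growth factor-binding protein Igfbp2 4.39-fold, the cell cycle phosphatase Cdkn3 4.35-fold and the cGMP-dependent kinase Prkg2 4.20-fold. Fndc1 rose 5.54-fold, but its call was lost without S1P replicate 6 or S1P replicate 8 (edgeR Benjamini-Hochberg adjusted p of up to 0.0523). Gm6166, a processed pseudogene whose transcript is 98.289% identical to Fabp5 over 409 bases, rose 4.80-fold. Its count was 0.432 to 0.553 of the Fabp5 count in each library, so its own change is uncertain.

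Among the largest decreases, Pi16, a peptidase inhibitor of fibroblasts (chromosome 17, 29455622 to 29466558), fell 10.8-fold, from 6.37 ± 2.11 to 0.579 ± 0.530 CPM (SD, n = 4 per group; log2 fold change -3.44, SE 0.52, edgeR Benjamini-Hochberg adjusted p = 0.00527). Mmp9, a gelatinase (chromosome 2, 164766080 to 164781550), fell 8.75-fold, from 18.6 ± 7.30 to 2.12 ± 0.871 CPM (edgeR Benjamini-Hochberg adjusted p = 0.00321). Ramp2, a partner of the calcitonin receptor-like receptor (chromosome 11, 101107142 to 101121060), fell 5.95-fold, from 16.55 ± 2.19 to 2.77 ± 0.878 CPM (edgeR Benjamini-Hochberg adjusted p = 0.00247). The cytokine receptor gene Il23r fell 6.63-fold, the kinase Wnk4 6.62-fold, the adhesion molecule Icam5 6.07-fold and the cytokine Csf3 6.04-fold. Ramp2 and Wnk4 lie beside each other on chromosome 11, where Wnk4 starts at 101121681. The span of Ramp2 shares 6240 bases with the untested gene Vps25 (mean of 0.3562 CPM), so its value is uncertain to that extent. The matrix protein Sned1 fell 9.40-fold and lost its call without S1P replicate 8 (edgeR Benjamini-Hochberg adjusted p = 0.0555). Serpina3n fell 5.23-fold and lost it without S1P replicate 6 or 8 (adjusted p of up to 0.086 in edgeR, Benjamini-Hochberg). Cfb and Prg4, whose spans overlap more abundant genes, fell 5.67-fold and 5.78-fold, and each was called in only 2 of the 8 fits that left out a library, those without vehicle replicate 1 or 4 (edgeR Benjamini-Hochberg adjusted p of up to 0.128 and 0.0907). Vehicle replicate 3 was high for Il23r at 8.07 CPM (other vehicle libraries 2.11 to 2.82), Serpina3n at 19.8 CPM (5.74 to 7.94) and Cfb at 16.8 CPM (2.83 to 4.38). It was also the highest vehicle library for Prg4 and Csf3. For Pi16, Sned1, Wnk4 and Ramp2 it was the lowest.

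Genes of mitosis moved together. Of 25 tested G2/M genes, 24 rose over all genes and 1 did not pass, and 25 rose adjusted over the list alone, with a median log2 fold change of 1.63. Ccnb2, a mitotic cyclin (chromosome 9, 70255296 to 70269561), rose 4.15-fold, from 25.6 ± 7.07 to 106 ± 11.7 CPM (SD, n = 4 per group; log2 fold change 2.05, SE 0.20, edgeR Benjamini-Hochberg adjusted p = 0.00247). Ccnb1, the other mitotic cyclin, rose 3.73-fold, Cenpa, the centromeric histone, 3.72-fold and Kif20a, a kinesin of cytokinesis, 3.71-fold. Plk1, chosen after its value was seen as the member that did not pass, had a log2 fold change of 1.25 (edgeR Benjamini-Hochberg adjusted p = 0.102). The mean of the list was 7.12 to 7.54 log2 CPM in the S1P libraries and 4.71 to 6.03 in the vehicle libraries. Of 26 tested G1/S and replication genes, 14 rose and 12 did not pass, and 19 rose adjusted over the list alone. Ccna2, the cyclin of S phase and G2, rose 3.18-fold, the ribonucleotide reductase genes Rrm1 and Rrm2 2.38-fold and 2.29-fold, and the replication factor Cdc45 2.32-fold. Both lists were called by camera (Benjamini-Hochberg adjusted p = 9.64e-46 and 1.33e-15), and neither was with an estimated correlation (adjusted p = 0.151 and adjusted p = 0.263 with an estimated correlation). The G1/S count was 7 without S1P replicate 6, 8 without S1P replicate 8, 23 without vehicle replicate 4 and 24 with a surrogate variable, and Cdc45 lost its call without S1P replicate 6 or 8 (edgeR Benjamini-Hochberg adjusted p of up to 0.059).

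**Figure D2:**
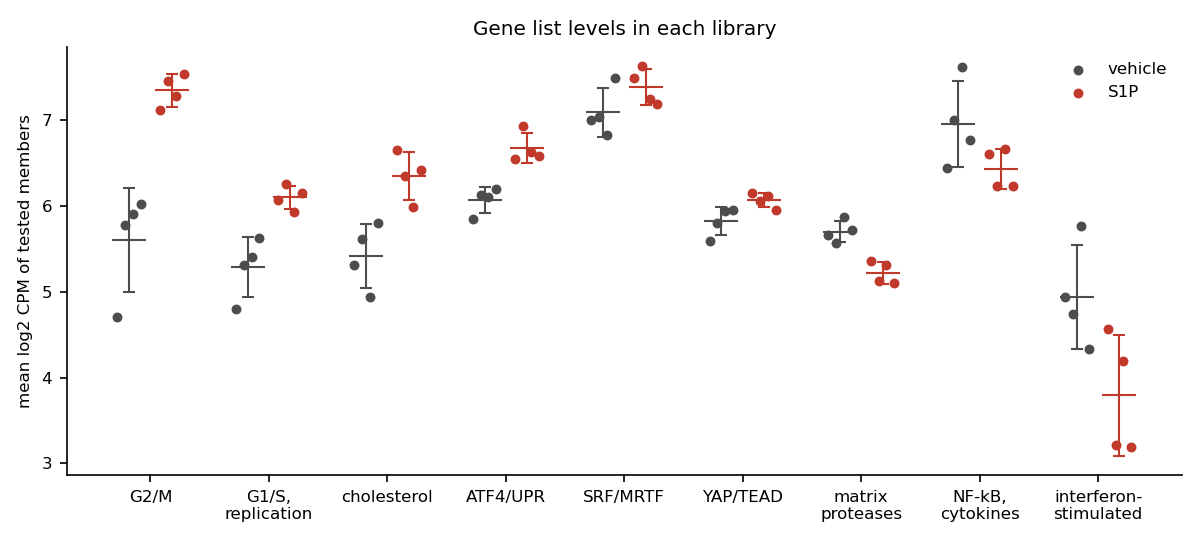
Each point is the mean log2 CPM of the tested members of a gene list (y axis) in a single library, with vehicle in grey and S1P in red, and the horizontal and vertical bars give the mean and SD of the 4 libraries of a group. The groups do not overlap for the G2/M, G1/S, cholesterol, ATF4 and protease lists and overlap for the NF-kB and interferon lists.

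Of 23 tested genes of cholesterol synthesis and uptake, 14 rose and 9 did not pass, and 17 rose adjusted over the list alone, with a median log2 fold change of 0.94. Fdps, which makes farnesyl diphosphate (chromosome 3, 88897314 to 88906081), rose 2.81-fold, from 58.8 ± 19.95 to 165 ± 45.9 CPM (SD, n = 4 per group; log2 fold change 1.49, SE 0.29, edgeR Benjamini-Hochberg adjusted p = 0.0144). Idi1, the isomerase one step before it, rose 2.66-fold, and Lss and Cyp51, which form and demethylate lanosterol, rose 2.56-fold and 2.54-fold. The list mean was 5.99 to 6.66 log2 CPM after S1P and 4.94 to 5.80 in vehicle. Camera called the list (Benjamini-Hochberg adjusted p = 1.5e-16), but not with an estimated correlation (adjusted p = 0.263 with an estimated correlation).

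Among ATF4 and unfolded protein response genes, 7 of 26 tested members rose and 19 did not pass, and 9 rose adjusted over the list alone. Psat1, an enzyme of serine synthesis (chromosome 19, 15978968 to 16022027), rose 3.59-fold, from 105 ± 37.1 to 377.5 ± 114.1 CPM (SD, n = 4 per group; log2 fold change 1.84, SE 0.30, edgeR Benjamini-Hochberg adjusted p = 0.007). Aldh1l2, a mitochondrial enzyme of one-carbon metabolism, rose 3.89-fold, the amino acid transporter Slc7a5 3.71-fold and the pseudokinase Trib3 3.93-fold. Camera called the list (Benjamini-Hochberg adjusted p = 6.41e-05), but not with an estimated correlation (adjusted p = 0.263 with an estimated correlation). The count was 12 with the GC and length offsets or a surrogate variable, 11 without both vehicle replicate 4 and S1P replicate 5, and 4 without S1P replicate 6. Without this last library Slc7a5 (adjusted p = 0.0517 in edgeR, Benjamini-Hochberg) also lost its call, as did Trib3 without any of vehicle replicates 2 and 3 and S1P replicates 6, 7 and 8 (adjusted p of up to 0.0936).

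Single contractile and matricellular genes rose, while most members of their lists did not pass the test. Of 26 tested SRF/MRTF genes, 5 rose and 21 did not pass, and 5 rose adjusted over the list alone. Besides Tagln, the smooth muscle actins Acta2 and Actg2 rose, Acta2 (chromosome 19, 34315380 to 34330026) 2.01-fold from 825 ± 49.9 to 1656 ± 499 CPM (SD, n = 4 per group; log2 fold change 1.00, SE 0.20, edgeR Benjamini-Hochberg adjusted p = 0.016) and Actg2 2.86-fold. The other risers were Filip1l, 1.63-fold, and Tpm4, a tropomyosin chosen after its value was seen, with a log2 fold change of 0.66. Of 24 tested YAP/TEAD targets, 3 rose and 21 did not pass, and 3 rose adjusted over the list alone. These were the matricellular genes Ctgf (chromosome 10, 24315048 to 24318689), 4.40-fold from 47.6 ± 20.9 to 209 ± 38.5 CPM, and Cyr61, 2.5-fold, and the muscle ankyrin repeat gene Ankrd1, 6.03-fold. Camera called the SRF/MRTF list (Benjamini-Hochberg adjusted p = 0.0328), but not with an estimated correlation (adjusted p = 0.698 with an estimated correlation), and did not call the YAP/TEAD list (adjusted p = 0.0966). Filip1l lost its call without vehicle replicate 2 or S1P replicate 6, 7 or 8 and Ankrd1 without vehicle replicate 1 or 2 or S1P replicate 6 (edgeR Benjamini-Hochberg adjusted p of up to 0.0913 and 0.059), and the span of Filip1l overlaps another expressed gene. The SRF/MRTF count was 3 without vehicle replicate 2 or S1P replicate 6, 7 or 8, and without vehicle replicate 4, or with the GC and length offsets, the counts were 8 SRF/MRTF and 7 YAP/TEAD genes. A surrogate variable gave 8 and 9, DESeq2 5 YAP/TEAD genes and the fit without both vehicle replicate 4 and S1P replicate 5 gave 9.

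**Figure D3:**
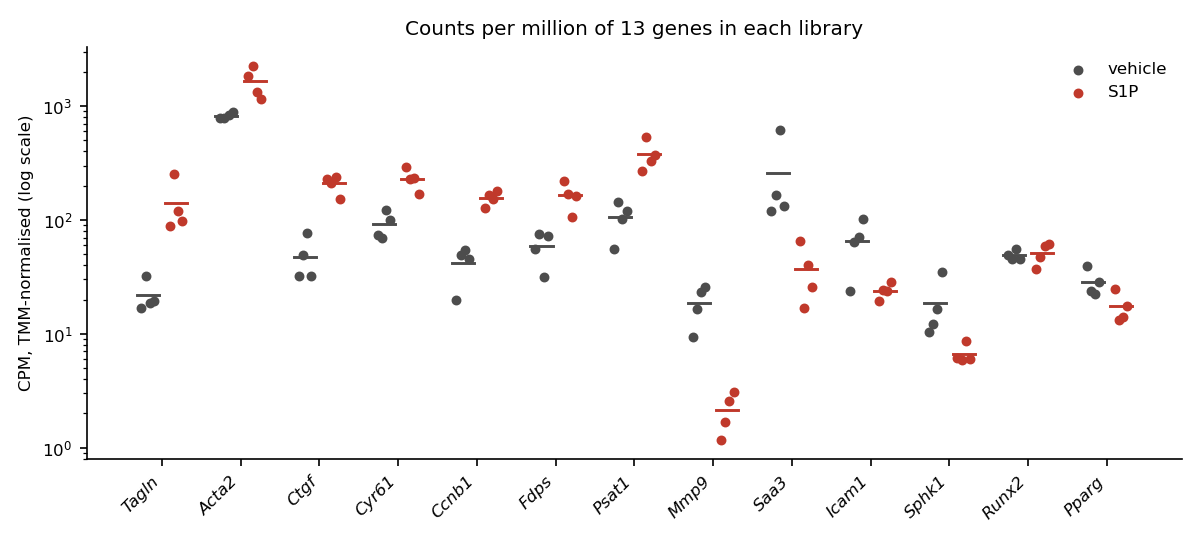
CPM of 13 genes (y axis, log scale) in each of the 4 vehicle libraries (grey) and 4 S1P libraries (red), with a bar at each group mean. Tagln, Acta2 and Ctgf sit higher in every S1P library than in any vehicle library, Mmp9 and Sphk1 sit lower, and Runx2 and Pparg overlap.

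Immediate early and ERK feedback genes went both ways, with 3 of 28 tested members higher and 2 lower, and 3 and 5 adjusted over the list alone. Etv4, an ETS factor downstream of ERK, rose 3.22-fold and the phosphatase Dusp5 2.28-fold. The remaining riser was the phosphatase Dusp4, chosen after its value was seen (log2 fold change 0.83). The Krüppel-like factors Klf2 and Klf4 fell 2.73-fold and 1.90-fold, Klf4 from 169.5 ± 34.3 to 89.05 ± 11.4 CPM (SD, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 0.0103). Camera did not call the list (Benjamini-Hochberg adjusted p = 0.125). Etv4 lost its call without S1P replicate 6 (edgeR Benjamini-Hochberg adjusted p = 0.0646), Klf2 without S1P replicate 6 or 7 (up to 0.0622) and Dusp5 in 6 of the 8 fits that left out a library (up to 0.0902), kept only without vehicle replicate 4 or S1P replicate 6. The count of risers was 1 without vehicle replicate 1, 2 or 3 or S1P replicate 6, 7 or 8, and the count of fallers was 5 with DESeq2, 4 without S1P replicate 5 and 1 without S1P replicate 6 or 7.

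Of 29 tested NF-kB targets, cytokines and chemokines, 5 fell and 24 did not pass, and 8 fell adjusted over the list alone, with a median log2 fold change of -0.55. Csf3, the granulocyte colony-stimulating factor gene (chromosome 11, 98562377 to 98565143), fell from 18.7 ± 10.5 to 3.08 ± 1.17 CPM (SD, n = 4 per group; log2 fold change -2.59, SE 0.48, edgeR Benjamini-Hochberg adjusted p = 0.0118). The acute-phase gene Saa3 fell 7.05-fold, from 261 ± 242 to 37.0 ± 21.2 CPM, the adhesion molecule Icam1 2.72-fold and the chemokine Ccl5 2.62-fold. The last was Tnfaip2, chosen after its value was seen (log2 fold change -0.84). Camera called the list (Benjamini-Hochberg adjusted p = 0.000223), but not with an estimated correlation (adjusted p = 0.594 with an estimated correlation). The count was 2 without vehicle replicate 2, 2 lower and 2 higher without vehicle replicate 3, 1 without S1P replicate 6, 7 or 8 and 9 without vehicle replicate 4. It was 9 with DESeq2, 11 with the GC and length offsets, 12 with a surrogate variable and 13 without both vehicle replicate 4 and S1P replicate 5. Saa3 lost its call without S1P replicate 6, 7 or 8 (edgeR Benjamini-Hochberg adjusted p of up to 0.0862), and Icam1 and Ccl5 lost theirs in 7 and 6 of the 8 fits that left out a library (up to 0.117 and 0.116), Icam1 keeping it only without vehicle replicate 1 and Ccl5 only without vehicle replicate 1 or 4. Vehicle replicate 3 held 623 CPM of Saa3, against 120 to 167 CPM in the other vehicle libraries. In the fits that left out a library, the log2 fold change of Saa3 ranged from -3.24 to -1.92.

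None of 25 tested interferon-stimulated genes passed the edgeR test over all genes with Benjamini-Hochberg adjustment, 19 were lower at an unadjusted p under 0.05, and 15 were lower adjusted over the list alone. The log2 fold change was negative for 24 of 25, with a median of -1.06. DESeq2 called 13 of them lower and limma-voom 3. The most abundant members were Gbp2, a guanylate-binding protein, at 299.6 ± 120.5 CPM in vehicle and 148 ± 63.2 after S1P, and Ddx58, a sensor of viral RNA, at 224 ± 55.3 and 164.5 ± 24.8 CPM (SD, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 0.119 and 0.177). Camera called the list (Benjamini-Hochberg adjusted p = 2.67e-08), but not with an estimated correlation (adjusted p = 0.543 with an estimated correlation). The list mean ranged from 4.33 to 5.77 log2 CPM in vehicle and from 3.19 to 4.57 after S1P, so the groups overlapped. Over all genes, 9 members were lower without vehicle replicate 4, 6 without S1P replicate 5, 20 without both, 11 with a surrogate variable and 4 with the GC and length offsets, and Gbp2 and Ddx58 passed without vehicle replicate 4 (edgeR Benjamini-Hochberg adjusted p = 0.0332 and 0.0427).

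Of 30 tested matrix and TGF-beta genes, 3 rose, 6 fell and 21 did not pass, and 5 rose and 9 fell adjusted over the list alone. Dcn, a small leucine-rich proteoglycan (chromosome 10, 96942045 to 96980977), fell 4.37-fold, from 72.8 ± 36.0 to 16.6 ± 6.29 CPM (SD, n = 4 per group; log2 fold change -2.13, SE 0.40, edgeR Benjamini-Hochberg adjusted p = 0.0125). Lum, of the same proteoglycan family, fell 4.70-fold and the lysyl oxidase Loxl2 4.68-fold. Risers included Tgfb3 and the tenascin gene Tnc, chosen after their values were seen, with log2 fold changes of 1.04 and 0.74. Of 19 tested proteases and inhibitors, 4 fell, 1 rose and 14 did not pass, and 6 fell and 1 rose adjusted over the list alone. Besides Mmp9, the fallers were the membrane protease Mmp14, 1.76-fold from 653 ± 123 to 372 ± 42.7 CPM, the aggrecanase Adamts4, 2.34-fold, and Mmp2, chosen after its value was seen (log2 fold change -0.60), while the plasminogen activator Plat rose 1.97-fold. Camera called the protease list (Benjamini-Hochberg adjusted p = 0.00368), but not with an estimated correlation (adjusted p = 0.151 with an estimated correlation), and did not call the matrix list (adjusted p = 0.28). Without S1P replicate 6 or 8, 1 protease was lower and 2 or 3 matrix genes were, and 1 matrix gene was higher without vehicle replicate 1 or 2 or S1P replicate 6, 7 or 8. Calls ended for Dcn without S1P replicate 6, for Mmp14 without S1P replicate 6 or 8, for Lum without S1P replicate 6, 7 or 8, for Adamts4 in the fits other than those without vehicle replicate 1 or S1P replicate 7, and for Plat in the fits other than those without vehicle replicate 1 or 4 (edgeR Benjamini-Hochberg adjusted p of up to 0.0525, 0.0551, 0.0716, 0.113 and 0.117).

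Of 26 tested S1P receptor, transporter and sphingolipid enzyme genes, 1 fell and 25 did not pass, while adjusted over the list alone none passed, with 5 lower at an unadjusted p under 0.05 in edgeR, 2 called by DESeq2 and none by limma-voom. There were 22 negative and 4 positive log2 fold changes. The gene that fell was Sphk1, which makes S1P (chromosome 11, 116392039 to 116398188), 2.80-fold from 18.6 ± 11.3 to 6.645 ± 1.302 CPM (SD, n = 4 per group; log2 fold change -1.48, SE 0.37, edgeR Benjamini-Hochberg adjusted p = 0.0409). The receptor genes S1pr1, S1pr2 and S1pr3 did not pass, at 61.2 ± 15.4, 108 ± 15.65 and 8.74 ± 5.36 CPM in vehicle and 43.6 ± 8.16, 84.4 ± 15.4 and 2.76 ± 1.13 CPM after S1P (edgeR Benjamini-Hochberg adjusted p = 0.188, 0.195 and 0.095). Sphk2, whose span overlaps the abundant gene Rpl18, was at 9.24 ± 6.93 and 6.92 ± 1.21 CPM, the lyase Sgpl1 at 324 ± 57.6 and 311 ± 15.9 CPM and the glucosylceramide synthase Ugcg at 385 ± 130 and 245 ± 53.5 CPM, and none of them passed. Camera called the list lower (Benjamini-Hochberg adjusted p = 0.0474), but not with an estimated correlation (adjusted p = 0.474 with an estimated correlation). The counts were 3 lower without vehicle replicate 1, 1 higher and 3 lower without vehicle replicate 4 or with the GC and length offsets, 1 higher and 4 lower with a surrogate variable, and 0 without vehicle replicate 3 or any single S1P library. In those last 5 fits the Sphk1 call was lost (edgeR Benjamini-Hochberg adjusted p of up to 0.129), while S1pr1 and S1pr3 passed without vehicle replicate 1 (adjusted p = 0.0416 and 0.0142) and Ugcg without vehicle replicate 4 (adjusted p = 0.031).

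Lineage regulators did not pass the test. The bone regulator Runx2 was at 48.8 ± 4.93 CPM in vehicle and 51.3 ± 11.1 CPM after S1P, the cartilage regulator Sox9 at 113 ± 36.1 and 95.1 ± 22.2 CPM and the fat regulators Pparg and Cebpa at 28.5 ± 7.645 and 17.5 ± 5.31 CPM and at 4.77 ± 2.99 and 4.715 ± 2.18 CPM (SD, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 0.811, 0.536, 0.114 and 0.988). Without S1P replicate 5, Pparg passed (edgeR Benjamini-Hochberg adjusted p = 0.0443). The bone regulator Sp7 lay below the 3-count limit in the mean of both groups and was not tested. None of 14 tested osteoblast genes changed by the edgeR test. Of these, 1 was higher and 2 lower at an unadjusted p under 0.05, 1 was higher and 1 lower adjusted over the list alone, and DESeq2 and limma-voom each called 1 higher and 1 lower. In edgeR, 2 were lower without vehicle replicate 4, 1 higher without vehicle replicate 1 and 1 lower without S1P replicate 5 or with the GC and length offsets, while a surrogate variable gave 2 lower. The abundant members, Col1a2 and Sparc, stood at 5319 ± 1285 and 4070 ± 884 CPM in vehicle. Of 17 tested adipocyte genes, the desaturase Scd1 rose 2.37-fold and the triglyceride enzyme Dgat2 fell 2.16-fold (1 and 2 adjusted over the list alone). The adipocyte genes that were lower numbered 3 without S1P replicate 5, with DESeq2, with a surrogate variable or without both vehicle replicate 4 and S1P replicate 5, and 0 without S1P replicate 6 or 8. Of 12 tested chondrocyte genes, the matrilin Matn3 rose 8.86-fold, from 0.367 ± 0.284 to 3.31 ± 2.19 CPM, and the lubricin gene Prg4 fell (1 and 1 adjusted over the list alone). Matn3 lay below the 3-count limit in vehicle replicates 1 and 2 (0.142 and 0.148 CPM), so the size of its rise is uncertain. Its groups also overlapped, with S1P replicate 5 at 0.722 CPM and vehicle replicate 3 at 0.740 CPM. Camera called none of these 3 lists (Benjamini-Hochberg adjusted p = 0.734, 0.116 and 0.28). Of the skeletal muscle genes, 1 was tested and did not pass, Mef2c, at 12.9 ± 10.35 and 10.5 ± 3.50 CPM. Matn3 lost its call without vehicle replicate 1 or 2 or S1P replicate 6, 7 or 8 and Dgat2 without S1P replicate 6 or 8 (edgeR Benjamini-Hochberg adjusted p of up to 0.0715 and 0.0564).

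Other signalling and metabolic lists held few changes, and camera called none of the 5 (Benjamini-Hochberg adjusted p of 0.102 to 0.647). Of 22 tested Wnt genes, 1 fell, Sfrp2, a Wnt inhibitor (log2 fold change -1.65), and the abundant members Rspo2 and Wisp2 did not pass. Of 17 tested BMP/SMAD1 targets, 1 rose, Hes1 (log2 fold change 0.81), and Bmpr1a and Fst did not pass. Of 25 tested glycolysis and hypoxia genes, 1 fell, Ndrg1 (log2 fold change -0.96), and Pkm2 and Ldha did not pass. Sfrp2, Hes1 and Ndrg1 were chosen after their values were seen. Of 22 tested FOXO and starvation genes, the 2 that changed were Foxo3 and Ypel3, which fell 1.46-fold and 1.73-fold. Of 24 tested p53 targets, the kinase Plk2 rose 1.81-fold, the ribosomal protein-like gene Rps27l 1.55-fold and the membrane protein Perp 2.93-fold, and the phospholipid transfer protein Pltp fell 3.05-fold. Adjusted over the list alone, 1 Wnt gene rose and 4 fell, 1 BMP/SMAD1 target rose, 1 glycolysis gene fell, 2 FOXO genes fell, and 3 p53 targets rose and 1 fell. The calls of Foxo3, Ypel3, Plk2, Rps27l, Perp and Pltp each ended without S1P replicate 6 and without S1P replicate 8 (edgeR Benjamini-Hochberg adjusted p of up to 0.135), and those other than Plk2 also ended without at least 1 further library. No Wnt gene was lower without vehicle replicate 2 or S1P replicate 5, 6 or 7, and no BMP/SMAD1 target was higher without vehicle replicate 2 or S1P replicate 7. Without vehicle replicate 4 there were 1 higher and 2 lower Wnt genes, 2 higher BMP/SMAD1 targets and 2 higher and 2 lower glycolysis genes. Higher and lower Wnt genes numbered 1 and 4 with a surrogate variable, 2 and 4 with the GC and length offsets and 1 and 3 with DESeq2. Glycolysis genes numbered 3 and 3, 3 and 1, and 1 and 2 in the same order, and DESeq2 called 2 BMP/SMAD1 targets and 4 FOXO genes lower. Without vehicle replicate 4, Wisp2 and Pkm2 passed (edgeR Benjamini-Hochberg adjusted p = 0.0118 and 0.0115).

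Of the endothelial markers, 5 were tested and none changed by edgeR, DESeq2 or limma-voom, 1 being lower at an unadjusted p under 0.05, with Flt1 at 124 ± 83.5 and 121.5 ± 47.1 CPM and Tek at 54.8 ± 20.8 and 31.2 ± 12.1 CPM in vehicle and S1P (SD, n = 4 per group). None of the 2 tested haematopoietic markers, Cd14 and Lyz2, or the 2 tested epithelial markers, Lamb3 and Cdh1, changed over all genes in edgeR or limma-voom. In each list 1 was lower at an unadjusted p under 0.05, adjusted over the list alone and by DESeq2, and Lamb3 passed without vehicle replicate 1 (edgeR Benjamini-Hochberg adjusted p = 0.0397). Of the 3 tested neural markers, Nes, an intermediate filament also found in progenitor cells, rose 2.67-fold, from 7.70 ± 2.395 to 20.6 ± 5.04 CPM (edgeR Benjamini-Hochberg adjusted p = 0.0103), and Stmn2 did not pass. None of 22 tested mitochondrially encoded and ribosomal protein genes changed by edgeR, DESeq2 or limma-voom or adjusted over the list alone, and none was at an unadjusted p under 0.05. Their most abundant members, mt-Co1 and mt-Cytb, were at 14550 ± 3171 and 15440 ± 781 CPM and at 7579 ± 1391 and 7707 ± 328.5 CPM.

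Camera did not call the endothelial list or the mitochondrial and ribosomal list (Benjamini-Hochberg adjusted p = 0.553 and 0.413). Over the 22 tested lists, camera with its preset correlation called 5 higher and 4 lower, and none held with an estimated correlation (adjusted p of at least 0.151 with an estimated correlation). By fry, which asks whether a list's own genes moved on balance to a single side, 4 lists were higher and 2 lower (Benjamini-Hochberg adjusted). By the exact permutation test of list means, the S1P libraries all lay on one side of the vehicle libraries for 6 lists, the G2/M, G1/S, cholesterol and ATF4 lists above and the protease and S1P receptor lists below. Each had the smallest p that 4 libraries against 4 can give (exact two-sided p = 0.029), and an adjusted p of 0.105 over the 22 lists.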

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

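The tests weighed here were chosen only after vehicle replicate 4 and the list results had been seen, apart from the splits of the libraries and the fits that left out a library, which were planned. Of 256 groups of 4 libraries, 21 held a library far from the other 3 (a gap to its nearest neighbour above 0.829 of the range), where chance alone gives about 1 in 20, or 12.8. For genes the gap was taken on log2 CPM, while plain CPM values are printed below. S1P replicate 5 was that library 7 times and vehicle replicate 4 was that library 5 times.

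Among vehicle libraries, replicate 4 stood low for Ankrd1 at 0.363 CPM (others 0.668 to 0.74), Rps27l at 68.1 CPM (98.2 to 105), mt-Co1 at 9820 CPM (15800 to 16400) and the mitochondrial share of counts at 2.5% (3.63% to 3.83%), and high for Sphk2 at 19.6 CPM (5.40 to 6.31). Replicate 1 stood high for Plat at 19.6 CPM (9.15 to 10.2) and low for Kif20a at 42.7 CPM (72.9 to 81.2) and Fst at 85.4 CPM (122 to 128). Replicate 2 stood high for Nes at 11.3 CPM (6.32 to 6.81). Among S1P libraries, replicate 6 stood high for Fabp5 at 108 CPM (52.5 to 58.5), its pseudogene Gm6166 at 52.9 CPM (28.0 to 29.4) and Igfbp2 at 24.6 CPM (12.4 to 13.7). Replicate 7 stood high for Ccl5 at 21.6 CPM (14.2 to 15.1) and Sphk1 at 8.59 CPM (5.89 to 6.14). Replicate 5 stood high for Pi16 at 1.37 CPM (0.287 to 0.367) and Mef2c at 15.7 CPM (8.36 to 8.98), and low for Prg4 at 0.289 CPM (0.862 to 1.02) and Plk2 at 313 CPM (456 to 476). In the same library the mean log2 CPM of skeletal muscle genes was 3.99 (3.09 to 3.19), that of p53 targets 6.09 (5.63 to 5.67) and that of endothelial markers 3.24 (4.09 to 4.23).

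Vehicle replicate 4 lay 1.41 times as far from the other vehicle libraries as the next library did. A treated library under a vehicle label is argued against by its position of 0.77 between the S1P mean at 0 and the mean of the other vehicle libraries at 1, over the genes that changed without it. With offsets for GC content and transcript length its distance ratio was 0.94, so a GC or length bias in that library is a candidate explanation. What brought such a bias about, and whether its cells also differed, was not tested.

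G2/M genes had a median log2 fold change of 1.63. Neither a single library nor a GC or length bias accounts for it, since the lowest median in the 8 fits that left out a library was 1.38 and the median with offsets was 1.58. Interferon-stimulated genes had a median of -1.06 although none passed the edgeR test over all genes, while 19 were at an unadjusted p under 0.05, DESeq2 called 13 and limma-voom 3. A single vehicle library or a GC or length bias is argued against in the same way, with a highest median of -0.78 in the fits that left out a library and a median of -1.13 with offsets. That S1P raised the former and lowered the latter stays a hypothesis, and a difference between cultures that runs with treatment stays open for both.

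The 8 libraries can be split into 4 and 4 in 35 ways. The real split gave 1007 changed genes and the highest of the other splits 0 by edgeR, so 1 of 35 splits gave as many. That is the smallest share possible, since the real split is counted. Every other split mixes vehicle and S1P libraries, which adds any group difference to the spread within groups and favours low counts. Chance is therefore argued against for this count only down to 1 of 35. A difference between cultures that runs with treatment is not addressed by the splits. The same held for genes changed at least 2-fold, with 520 against 0 (1 of 35). For the number of gene lists called by camera with its preset correlation, 9 in the real split, 16 of 35 splits gave as many or more and the highest gave 16, so chance cannot be excluded for that number.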

How the results depend on the processing

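The offsets for GC content and length and the fit without vehicle replicate 4 and S1P replicate 5 together were chosen after the data had been seen, and the rest was planned. No paired fit was made, because the labels give no pairing and the replicate numbers are not shared between the groups. The correlations in label order given at the end leave a pairing open, and its effect on the counts was not tested. None of the 1007 genes changed sign under any composition factor, filter, tool, offset or left-out library. This was a weak test, since they were chosen on the same counts and in 985 of them the groups did not overlap. Without S1P replicate 6, 433 of them were still called. The 1007 genes included 942 of the 975 genes called with RLE factors, 950 of 1025 with limma-voom and 1005 of 1771 with DESeq2. Higher genes made up 56.1% of calls with upper-quartile factors. DESeq2 gave 804 lower genes and 330 at least 2-fold lower, with 60 adjusted p-values not given. A surrogate variable gave 1471 higher and 1015 lower, the offsets 1011 and 696, and the fit without both libraries, which had fewer samples, 1178 and 934, with 345 at least 2-fold lower. The cause of these gains was not tested. Tested against a 1.5-fold change, a stricter question by construction, 150 genes were higher and 35 lower. With an estimated correlation 0 lists were higher and 0 lower by camera, where 5 and 4 were at the preset correlation, and by fry 2 were lower. Leaving out each library gave 333 to 1133 higher genes, 101 to 723 lower and 69 to 220 at least 2-fold lower, lowest without S1P replicate 6 and highest without vehicle replicate 4. Of 68 named genes that passed, 38 passed in all 8 of these fits.

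Log2 fold changes of named genes, and camera directions of lists, turned only where they had not passed, and the cause was not tested. With upper-quartile factors they were Col1a2 at -0.015 and mt-Cytb at -0.028. With limma-voom they were Flt1 at 0.195, Cdh1 at 0.004 and Cebpa at 0.062. With a surrogate variable they were Cdh1 at 0.097, mt-Cytb at -0.036, Sphk2 at 0.072 and Cebpa at 0.319. With the offsets they were Bmpr1a at -0.059, Fst at -0.043, Flt1 at 0.018, Cdh1 at 0.003, Stmn2 at -0.081, mt-Co1 at -0.109, mt-Cytb at -0.166, Sphk2 at 0.085 and Cebpa at 0.528. Without both libraries they were Flt1 at 0.08, Cdh1 at 0.131, mt-Co1 at -0.082, mt-Cytb at -0.118, Sphk2 at 0.178, Cebpa at 0.713 and Sox9 at 0.073, and camera turned for the chondrocyte genes, with a median of 0.132, and the BMP/SMAD1 targets, with a median of 0.136.

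Across the fits that left out a library, ranges that crossed 0 included -0.166 to 0.016 for Sgpl1, -0.089 to 0.201 for Col1a2, -0.063 to 0.214 for Sparc, -0.553 to 0.418 for Mef2c, -0.004 to 0.181 for Bmpr1a, -0.022 to 0.216 for Fst, -0.034 to 0.344 for Ldha and -0.371 to 0.462 for Flt1. They were -0.257 to 0.157 for Cdh1, -0.286 to 0.505 for Stmn2, -0.063 to 0.149 for mt-Co1, -0.095 to 0.104 for mt-Cytb, -0.632 to 0.261 for Sphk2, -0.019 to 0.198 for Runx2, -0.299 to 0.493 for Cebpa and -0.24 to 0.079 for the median of BMP/SMAD1 targets. Other list medians crossed 0 too, at -0.37 to 0.1 for glycolysis and hypoxia genes, -0.17 to 0.07 for matrix genes, -0.17 to 0.06 for osteoblast genes, -0.17 to 0.01 for FOXO genes and -0.08 to 0.2 for p53 targets.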

Other observations

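The 5 gene lists and the tests of this part were all chosen after the results had been seen, so their counts and p-values are not independent evidence. Fisher's exact test also treats genes as independent, which genes that move together are not. Complement genes were among those that fell. Of 15 tested components and regulators, 9 fell and 1 rose, with a median log2 fold change of -1.42 (Fisher's exact test for lower genes against all tested genes, two-sided p = 5.69e-11). C3, the central complement component (chromosome 17, 57343193 to 57367759 in mm9), fell 3.97-fold, from 4677 ± 1752 to 1178 ± 415 CPM (SD, n = 4 per group; log2 fold change -1.99, SE 0.35, edgeR Benjamini-Hochberg adjusted p = 0.00929). Cd55, which protects cells from complement, fell 4.86-fold, and Masp1, a protease of the lectin pathway, rose 3.30-fold. The span of C1rb (mean of 7.2 CPM) overlaps those of C1ra (213.7 CPM) and C1s (619 CPM), and C1s also overlaps Gm5077 (72.05 CPM). The separate values of these genes are uncertain to that extent. The count of lower members was 5 without vehicle replicate 3, 4 without S1P replicate 6 or 7 and 2 without S1P replicate 8.

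Of 19 tested genes of antigen processing and presentation, 9 fell, with a median log2 fold change of -0.87 (Fisher's exact two-sided p = 9.48e-10), and the count was 3 without S1P replicate 6 or 8 and 4 without S1P replicate 7. Among them were Tap1, a peptide transporter, which fell 1.91-fold, the immunoproteasome subunit Psmb8, 3.40-fold, and Cd74, the invariant chain, 2.70-fold. Of 26 tested Fanconi and homologous recombination genes, 18 rose, with a median of 1.14 (Fisher's exact two-sided p = 2.39e-17), and leaving out a library gave 14 to 20. Brca1 rose 2.48-fold and Fancd2 2.93-fold, and their spans overlap the more abundant genes Nbr1 and Tmem111. All 4 tested collagen VI chains fell, with a median of -1.48 (Fisher's exact two-sided p = 7e-07), and 1 fell without S1P replicate 6 or 8. Col6a1, also a member of the matrix list and the most abundant of them, fell 2.00-fold from a vehicle level of 1962 ± 473 CPM. Col6a6 averaged 0.201 CPM after S1P, below the 3-count limit, so its log2 fold change of -2.78, which enters the median, is uncertain. In the fatty acid-binding protein cluster on chromosome 3, Fabp5 and Pmp2, already named among the largest increases, rose (Fisher's exact two-sided p = 0.00904). Fabp4 had a log2 fold change of 1.37 without passing (edgeR Benjamini-Hochberg adjusted p = 0.197).

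Among 123 families of genes that share the start of their symbol, 5 were enriched among higher genes and 2 among lower genes (Fisher's exact test, Benjamini-Hochberg adjusted over 246 tests). Higher were 12 of 28 Kif genes, the kinesins (adjusted p = 2.8e-06), 8 of 19 Nup genes, the nucleoporins (adjusted p = 0.000248), 8 of 19 Rad genes (adjusted p = 0.000248), 7 of 20 Cep genes (adjusted p = 0.00279) and 4 of 10 Mcm genes (adjusted p = 0.0479). Lower were 7 of 31 Col genes, the collagens (adjusted p = 0.00116), and 6 of 28 Il genes (adjusted p = 0.00443). By camera with Benjamini-Hochberg adjustment none held with an estimated correlation (adjusted p = 0.165 with an estimated correlation for Kif, 0.692 for Nup, Rad, Cep and Mcm, and 0.724 for Col and Il). The 4 collagen VI chains given above are among the lower Col genes. The Kif, Mcm and Rad families share members with the G2/M, G1/S and Fanconi lists. These families therefore partly count the same genes again and are not separate findings.

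Deviations from the group means correlated across 11844 genes, which are not independent replicates, at 0.54 between vehicle replicate 1 and S1P replicate 5, 0.13 between 2 and 6, 0.56 between 3 and 7 and 0.19 between 4 and 8, and the mean of 0.35 for this order ranked 2 of 24 pairings, the highest being 0.39.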
